A study of Danio rerio with 20 samples.

How the data were processed

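Direct RNA reads of poly(A) RNA from whole zebrafish embryos were analysed: 20 samples that form 18 libraries in 9 groups of 2. Groups were set from the labels. The deposited per-read tables name merged replicates, and each merge is 1 library here. Per the labels, embryos were kept at 28 °C and 1 nL was injected at the 1-cell stage. The α-amanitin and tinyLNA embryos were collected at 6 hpf, so wild type at that age from the time course is their control. Within the MZythdf2 table the sibling libraries carry wild-type names, and they were taken as the siblings the labels describe.

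The authors aligned the reads to GRCz11 with minimap2 2.17-r941 and SAMtools and deposited 1 table of reads per experiment, with the counts of m6A calls on each read, per the file headers. The same deposited tables give read and aligned lengths in nucleotides, start, end and call positions as genomic coordinates, a gene identifier per read, and tail lengths in nucleotides from tailfindr, blank where none was found. A deposited site table of the time course holds coverage as counts of reads, the modified share as a fraction of the reads at each site, and the authors' status per site, per the file headers. The m6A caller, its probability threshold and the rule for calling a site replicable are not given in the sources used here. Deposited filtered tables hold identifiers of reads the authors kept. In that of the time course the 4 hpf reads also stand under the 6 hpf label, so uniquely assigned reads with a tail were used in its place.

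Reads assigned to 1 gene were counted per library with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and pyarrow 21.0.0. Gene changes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) in R 4.3.3, with 1 model per experiment and Benjamini-Hochberg adjustment at an FDR of 0.05. The comparisons were 6 against 2, 4 against 2 and 6 against 4 hpf in wild type, MZythdf2 against sibling at 2 and at 6 hpf, their interaction, 6 against 2 hpf within each genotype, each injection against wild type, and the injections against each other. A fold against a group without reads is a bound at a floor of 3 reads over the group. With 1 to 3 reads, the ratio is given with its 95% counting interval.

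Gene lists were fixed from general knowledge before the data were examined: m6A machinery, mRNA decay, poly(A) binding and translation, oocyte and maternal genes, germ plasm, first-wave zygotic genes, maternal transcription factors, enveloping layer, yolk syncytial layer, cell cycle, known miR-430 targets, p53 and stress, ribosomal proteins, mitochondrially encoded genes, and adult ovary and blood markers. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The genes named are, by a rule set before the data were examined, ythdf2 in MZythdf2 comparisons, up to 3 members per list with the smallest adjusted p past the FDR, and the 5 largest changes each way with a mean of at least 20 reads per library in the higher group and no overlap, ranked by fitted values. For sites and tails it was the 5 largest each way. A gene named in 1 comparison was followed in others. Some genes this rule names are not reported here.

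Sites were tested by quasi-binomial models with limma's squeezed dispersions at a coverage of at least 25 in every library. In the time course the deposited coverage and fraction were used. In the other tables reads over deposited sites were counted here, at sites where counted reads stayed within 1.2 times the deposited coverage in the time course. Median tails per gene (at least 10 reads per library) were tested on the log2 scale with limma. Shares of modified reads and median tails per library were compared by exact permutation. The lists of called sites differ between the tables of the 3 experiments, so shares of modified reads per library are compared only within a table. Site tests of α-amanitin and tinyLNA against wild type compare reads of 2 tables, at sites with a call in the table of the injected embryos.

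Depth ran from 173793 to 6452368 reads per library. With 2 simulated libraries per group, edgeR recovered 60% to 95% of 4-fold and 9% to 48% of 2-fold changes, least in the interaction. At most 6.06% of its calls were false. Simulated site changes were recovered at 69% to 84.5% with at most 7.38% false calls, and 2-fold tail changes at 87% to 91% with at most 8.08%, while tail changes of 0.5 log2 were recovered at 4% to 51%. Of 20 unchanged simulated lists up to 2 were called at the preset correlation and 0 with an estimated one. Intervals on single shares cover counting error only. Replicate libraries were checked for duplication: chi-square per degree of freedom ran from 1.158 to 10.58. MZythdf2 and sibling pairs, at 1.158 to 1.886, differed little beyond counting error.

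Alternatives set before the data were examined were RLE scaling, no filter on counts, DESeq2 1.42.0, a fit of the 2 groups alone, uniquely assigned reads with a tail, replicate numbers as blocks, each replicate left out, Fisher's exact test on pooled reads, a coverage of 10, mean tails, 20 reads, tails of 10 to 250 nt, equal weight per gene, reads over 500 nt, genes matched on expression and read length, and classes by the share of modified reads. Chosen after seeing the data were: mitochondrial genes or ribosomal protein genes left out, the trend on read length removed, classes of genes by site position, sites shared by the 3 tables, nuclear reads, sites of at least 10% at 2 hpf, reads counted here in place of deposited coverage, read-length classes, and replicates left out for lists. With a replicate left out, the lone library of a group was assumed to vary like the other groups. Lists of miR-430 seed matches and classes of sites by transcript region need transcript annotation and were not run. Figures were drawn with matplotlib 3.10.9, and binomial intervals of single shares used scipy 1.17.1.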

Results

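Poly(A) RNA of whole zebrafish embryos was read molecule by molecule on Nanopore flow cells, and each read carries the m6A calls and the poly(A) tail length found on it. Wild-type embryos form a time course at 2, 4 and 6 hours post fertilization (hpf). Further wild-type embryos received 0.2 ng of α-amanitin, an inhibitor of RNA polymerase II, or 10 µM of a tinyLNA against the seed of the microRNA miR-430 at the 1-cell stage, and were collected at 6 hpf. Embryos that lack maternal and zygotic Ythdf2 (MZythdf2), a cytoplasmic protein that binds m6A in mRNA, were collected with wild-type siblings at 2 and 6 hpf. Each of the 9 groups holds 2 libraries. Replicates 1 and 2 of wild type at 6 hpf were merged, as were tinyLNA replicates 2 and 3.

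Depth was 6256286 and 6452368 reads for wild type at 2 hpf, 3265329 and 2780343 at 4 hpf and 2565619 and 2448827 at 6 hpf. The α-amanitin libraries held 521561 and 382557 reads and the tinyLNA libraries 667932 and 660017. Sibling libraries held 258361 and 255749 reads at 2 hpf and 173793 and 177469 at 6 hpf, and MZythdf2 libraries 470803 and 417451 at 2 hpf and 333437 and 323551 at 6 hpf. Nothing in the labels says that replicates came from separate clutches, so p-values measure only the spread between these libraries. Values after a gene are its log2 fold change with standard error (SE) and adjusted p from edgeR, and levels are CPM (edgeR counts scaled to normalised library size) as mean ± SD (n = 2 libraries). These are relative levels within the poly(A) RNA of a library.

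The first comparison asks which maternal mRNAs were cleared and which zygotic mRNAs appeared between 2 and 6 hpf in wild type. Of the oocyte and germ-plasm mRNAs 19 of 33 and 10 of 14 fell, and 69 of 71 genes of the first zygotic wave, 18 of 19 of the enveloping layer and all 12 of the yolk syncytial layer rose. These list calls passed at the preset correlation only. The mRNA of btg4 (ENSDARG00000035171), an adaptor that brings the CCR4-NOT deadenylase to maternal mRNA, fell from 919 ± 30.0 to 28.1 ± 8.59 CPM (-5.03, SE 0.32, adjusted p = 6.85e-08). Germ-plasm organizer buc (ENSDARG00000096095) fell from 759 ± 3.83 to 31.6 ± 10.8 (-4.58, SE 0.28, adjusted p = 4.75e-08). The apolipoprotein gene apoeb (ENSDARG00000040295) rose from 0.541 ± 0.172 to 4321 ± 451 (12.88, SE 0.46, adjusted p = 2.82e-09).

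Of 33 measured oocyte and maternal genes 19 fell and 4 rose (median -1.54, adjusted p = 7.89e-06; adjusted p = 0.161 with an estimated correlation), and the same numbers passed when adjusted over the list alone. They include slbp2, an oocyte form of the histone stem-loop binding protein (-4.22, SE 0.30). Among 14 germ-plasm genes 10 fell and 1 rose (median -1.93, adjusted p = 0.000389; adjusted p = 0.0979 with an estimated correlation), also when adjusted over the list alone, with the Tudor-domain gene TDRD6 at -3.87 (SE 0.29) and rgs14a at -3.01 (SE 0.29). Of 71 first-wave zygotic genes 69 rose and 1 fell, the same when adjusted over the list alone, with a median of 9.32, or 8.35 with genes absent in 1 group at their bound (adjusted p = 6.18e-63; adjusted p = 0.0979 with an estimated correlation). Among them were the hatching-gland and enveloping-layer factor klf17 (8.35, SE 0.32) and the BMP-responsive id1 (8.53, SE 0.31). All 12 yolk-syncytial-layer genes rose (median 9.39, 7.77 at bounds, adjusted p = 1.34e-16; adjusted p = 0.0979 with an estimated correlation), also when adjusted over the list alone. Endoderm factor gata6 reached 309 ± 72.7 from 5.23 ± 0.479 (5.87, SE 0.28), and hnf4a, at 1 read in each 2 hpf library, was 1530-fold higher (95% interval 423 to 12700). Of 19 enveloping-layer genes 18 rose and 1 fell, with the same numbers adjusted over the list alone (median 11.33, 9.66 at bounds, adjusted p = 6.83e-28; adjusted p = 0.0979 with an estimated correlation). The epidermal antigen lye rose to 2537 ± 41.0 from 0.339 ± 0.0836, and the keratin cyt1, with 0 reads at 2 hpf, was at least 2410-fold higher.

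Ribosomal protein genes also rose, 83 of 90 with 5 lower and the same numbers adjusted over the list alone (median 1.76, adjusted p = 4.98e-15; adjusted p = 0.24 with an estimated correlation). That list includes 10 ribosomal S6 kinase genes caught by its name pattern. Tails of ribosomal protein mRNAs also lengthened over this interval, from a median of 29.4 to 71.8 nt. Whether tail length alters how many of their reads are captured as poly(A) RNA was not tested. Among 13 known miR-430 targets 7 rose and 4 fell, also when adjusted over the list alone (median 1.97, adjusted p = 0.0317; adjusted p = 0.195 with an estimated correlation), led by the Nodal antagonist lft2 (at least 261-fold higher). Over 7 alternatives this adjusted p ran from 0.0339 to 0.0749, and it passed 0.05 without wild-type 2 hpf replicate 2 (0.0608), without 6 hpf replicate 1 (0.0749) and with replicate numbers as blocks (0.0571). Of 14 p53 and stress genes 9 rose and 2 fell, the same adjusted over the list alone (median 1.34, adjusted p = 0.0334; adjusted p = 0.349 with an estimated correlation), with the small heat-shock gene hspb1 at 7.39 (SE 0.33). That call ended without 6 hpf replicate 3 (0.0502, range over 7 alternatives 0.00891 to 0.0502).

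Lists whose test did not pass still held changed members. Of 18 genes of the m6A machinery 7 rose and 6 fell (adjusted p = 0.903), with the readers igf2bp1 (2.23, SE 0.23) and ythdf2 (1.98, SE 0.27, adjusted p = 4.79e-05) higher. Of 25 mRNA decay genes 8 rose and 11 fell (adjusted p = 0.22), among the latter the zinc-finger gene cth1 (-2.54, SE 0.26). Poly(A)-binding and translation genes gave 6 higher and 2 lower of 12 (adjusted p = 0.261), with the Y-box gene ybx1 at 2.91 (SE 0.27). Among 9 maternal transcription factors 4 rose and 2 fell (adjusted p = 0.364), with pou5f3 at 2.57 (SE 0.23), vrtn at 2.33 (SE 0.23) and sox19b at -2.96 (SE 0.33). Cell-cycle genes split 18 higher and 11 lower of 44 (adjusted p = 0.277), with the replication helicase gene mcm3 at 8.58 (SE 0.37) and cyclin gene ccne2 at 6.19 (SE 0.33). Of 13 mitochondrially encoded genes 9 rose and none fell, 10 when adjusted over the list alone (adjusted p = 0.104). Adult ovary and blood markers were too few to test, and hbaa2, a haemoglobin gene, was at least 50.2-fold higher at 6 hpf on 23 and 9 reads.

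Over 13194 tested genes 4133 rose and 4497 fell at a false discovery rate (FDR) of 0.05, 7169 of them over 2-fold, with the median gene at -0.151. Ranked by fitted values, which are no bounds where 1 group has no reads, the top increases were krt18a.1 (at least 14000-fold), si:ch211-152c2.3 (at least 11700-fold), asb11 (at least 7730-fold), the claudin cldne (at least 6590-fold) and zgc:193505 (at least 6290-fold). The top decreases were PLEKHG5 (at least 23.9-fold), hivep1 (at least 20.1-fold), ppp1r16a (at least 18.1-fold), tshz3a (at least 15.8-fold) and HOXB2 (at least 15.2-fold). The 9411 genes with an m6A site had a median log2 fold change of -0.332 against 0.079 for the 2529 genes without one, and 39.6% of them fell against 26.7% (camera with preset correlation, p = 0.0176). Between 2351 genes of each class matched for expression and length the difference was -0.414 log2, as large as the -0.411 among all, but its p was 0.363. With the trend on read length removed the difference was -0.229 (camera with preset correlation, p = 0.188).

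**Figure D1:**
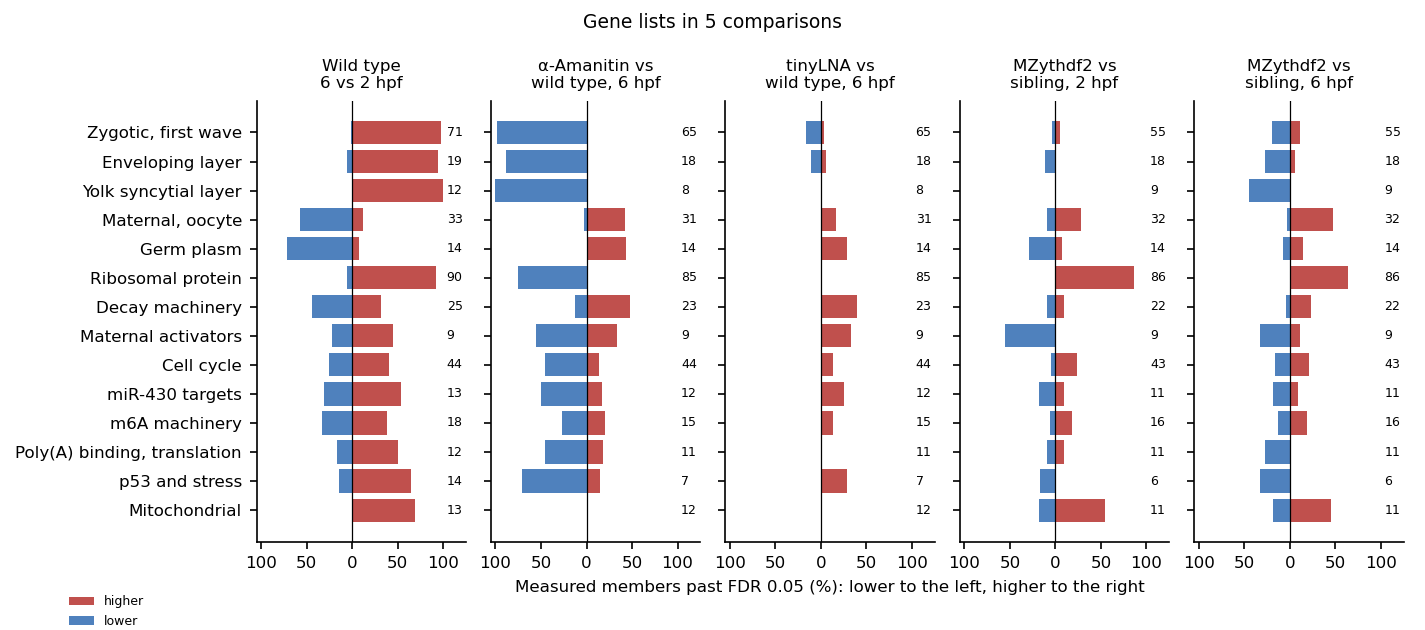
Share of measured members of each gene list past FDR 0.05 (x axis, percent; higher to the right, lower to the left) in 5 comparisons, with the number of measured members at the right of each bar. First-wave genes rose from 2 to 6 hpf (69 of 71) and were lower with α-amanitin (64 of 65).

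At 4 hpf against 2 hpf, the question was which of these changes had begun. First-wave genes rose for 54 of 71 with 1 lower, 57 and 2 when adjusted over the list alone (median 6.01, 5.78 at bounds, adjusted p = 2.84e-104; adjusted p = 0.0936 with an estimated correlation). The Hairy-family repressor gene her5 reached 214 ± 12.3 from 0.471 ± 0.271 (8.72, SE 0.33, adjusted p = 2.61e-08), and the yolk-syncytial factor mxtx2 was at least 595-fold higher. Enveloping-layer genes rose for 11 of 19, 13 when adjusted over the list alone (median 4.42, 2.5 at bounds, adjusted p = 9.7e-23; adjusted p = 0.0936 with an estimated correlation), and 5 of 12 yolk-syncytial genes rose (median 3.05, 1.76 at bounds, adjusted p = 1.1e-06; adjusted p = 0.145 with an estimated correlation). Oocyte genes fell for 10 of 33, 16 when adjusted over the list alone (median -0.54, adjusted p = 1.77e-05; adjusted p = 0.144 with an estimated correlation), among them org (-2.21, SE 0.33), buc2l (-1.91, SE 0.28) and slbp2 (-1.37, SE 0.24). Of 14 germ-plasm genes 4 fell, 5 when adjusted over the list alone (adjusted p = 0.00246; adjusted p = 0.14 with an estimated correlation), including dazl (-1.53, SE 0.27). Known miR-430 targets rose for 5 of 13, 6 adjusted over the list alone (adjusted p = 5.12e-05; adjusted p = 0.0936 with an estimated correlation), and p53 genes for 5 of 14 (adjusted p = 0.00636; adjusted p = 0.373 with an estimated correlation). None of 90 ribosomal protein genes passed in edgeR.

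In total 697 genes rose and 675 fell by 4 hpf, 1145 of them over 2-fold, with inka1a (at least 1480-fold) and si:zfos-44a5.1 (at least 1030-fold) among the largest increases and dck, a deoxynucleoside kinase (-3.87, SE 0.40), among the decreases. The count was 683 without wild-type 2 hpf replicate 1, 612 without replicate 2 and 603 without 4 hpf replicate 2. Genes with an m6A site differed from those without by 0.064 log2 (camera with preset correlation, p = 0.389), and matched genes by -0.059 (p = 0.981).

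From 4 to 6 hpf 3721 genes rose and 3843 fell (median gene -0.143). Oocyte genes fell for 18 of 33 and rose for 8, 19 and 8 when adjusted over the list alone (median -0.99, adjusted p = 0.000532; adjusted p = 0.204 with an estimated correlation), with btg4 at -3.93 (SE 0.31) and buc at -3.51 (SE 0.27). Ribosomal protein genes rose in this interval, 83 of 90 with 5 lower and the same adjusted over the list alone (median 1.76, adjusted p = 4.88e-24; adjusted p = 0.204 with an estimated correlation). Of 12 yolk-syncytial genes 11 rose and 1 fell, the same adjusted over the list alone (adjusted p = 1.36e-13; adjusted p = 0.155 with an estimated correlation), with mttp at 8.07 (SE 0.47). The keratin krt17 (at least 346-fold) and the somite factor mespab (at least 354-fold) also rose. Mitochondrially encoded genes rose for 10 of 13 (adjusted p = 0.0132; adjusted p = 0.534 with an estimated correlation), a call that ended without 6 hpf replicate 1 (0.0824, range over 7 alternatives 0.000259 to 0.0824).

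The share of reads with at least 1 m6A call was compared over the same time course. It was 23.8 ± 0.338% at 2 hpf, 23.2 ± 1.12% at 4 hpf and 18.8 ± 0.272% at 6 hpf (SD, n = 2), a decline over time with an exact permutation p = 0.0444 over 90 arrangements, two-sided. From 2 to 6 hpf the difference was -5.01 points, -2.96 with equal weight per gene (exact permutation p = 0.0889 for the decline) and -0.565 at sites shared by the 3 site lists (exact permutation p = 0.911). Counting error was small beside this: at 2 hpf replicate 1 stood at 23.6% (95% Wilson interval 23.5 to 23.6). Gene groups differed in level, in shares pooled over reads whose genes change between the ages. First-wave mRNAs carried a call on 67.3 ± 0.295% of reads at 2 hpf, from 55 genes and 3748 reads in replicate 1, and on 42.3 ± 0.608% at 6 hpf, from 71 genes and 37446 reads. The shares were 22.2 ± 0.479% and 12.7 ± 0.293% for oocyte mRNAs, and for ribosomal protein mRNAs 1.83 ± 0.137% and 1.01 ± 0.122%. Over 9185 nuclear genes with at least 20 reads in both groups the share went from 24.8% to 19.5%, and 6 hpf reads given the 2 hpf shares of their genes gave 21.5%.

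At single sites of the GRCz11 genome, 16 of 12017 tested sites rose and 69 fell from 2 to 6 hpf. The site in the splicing-factor mRNA srsf5a (chromosome 13, position 36530623, minus strand) went from 53.2% of 371 and 420 reads to 25.2% of 2958 and 3152 reads (adjusted p = 0.000433). The site in krcp (chromosome 7, position 24887701) fell by 27.55 points, that in the RNA cyclase rtca (chromosome 22, position 16282864) fell by 25.04 and that in plekhm1 (chromosome 12, position 4962326) fell by 30.5. Among the 5 largest increases were zbedx (chromosome 6, position 16475150; 23.1% to 51.8%) and sall4, a pluripotency factor (chromosome 23, position 38946655; 3.82% to 22.9%). The count was 6 and 9 without either 2 hpf library, 20 and 10 without 6 hpf replicates 1 and 3, and 225 without either 4 hpf library. In the deposited site table the authors list 4482 sites as increased, 9815 as decreased and 24561 without change from 2 to 6 hpf. Of the 85 sites called here 11 and 35 carry the same direction there, none the opposite and the rest no change. Both use the same libraries, so this is no independent check.

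Tails lengthened with time: the median tail of nuclear reads was 43.1 ± 1.1 nt at 2 hpf, 62.1 ± 10.1 nt at 4 hpf and 66.4 ± 7.71 nt at 6 hpf (SD, n = 2; exact permutation p = 0.0444 over 90 arrangements). Ribosomal protein mRNAs stood out, with 80 of 87 longer and 1 shorter by limma (29.4 to 71.8 nt). First-wave mRNAs with enough reads lengthened for 9 of 12 (29.7 to 60.1 nt) and cell-cycle mRNAs for 22 of 42 with 9 shorter (40.6 to 65.9 nt). The mitotic kinase mRNA melk went from 16.1 to 96.3 nt (log2 difference 2.56, SE 0.20, adjusted p = 2.77e-05) and chaperone hspe1 from 18.2 to 104 nt. Among shortened mRNAs, nanog, a maternal activator of the zygotic genome, went from 125 to 32.2 nt (-1.95, SE 0.16, adjusted p = 2.77e-05) and the calpain CAPN1 from 130 to 28.2 nt. None of 12 mitochondrial mRNAs passed. Of 8189 genes 3136 were longer and 1431 shorter. The count of changed tails was 2542 and 2826 without 2 hpf replicates 1 and 2, and the other large decreases (ENSDARG00000102550, si:cabz01071911.3 and dhx9) rested on a median of 1 nt in 6 hpf replicate 3. Of these, dhx9 stood at -2.51 (SE 0.99) and at -0.24 without that replicate.

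**Figure D2:**
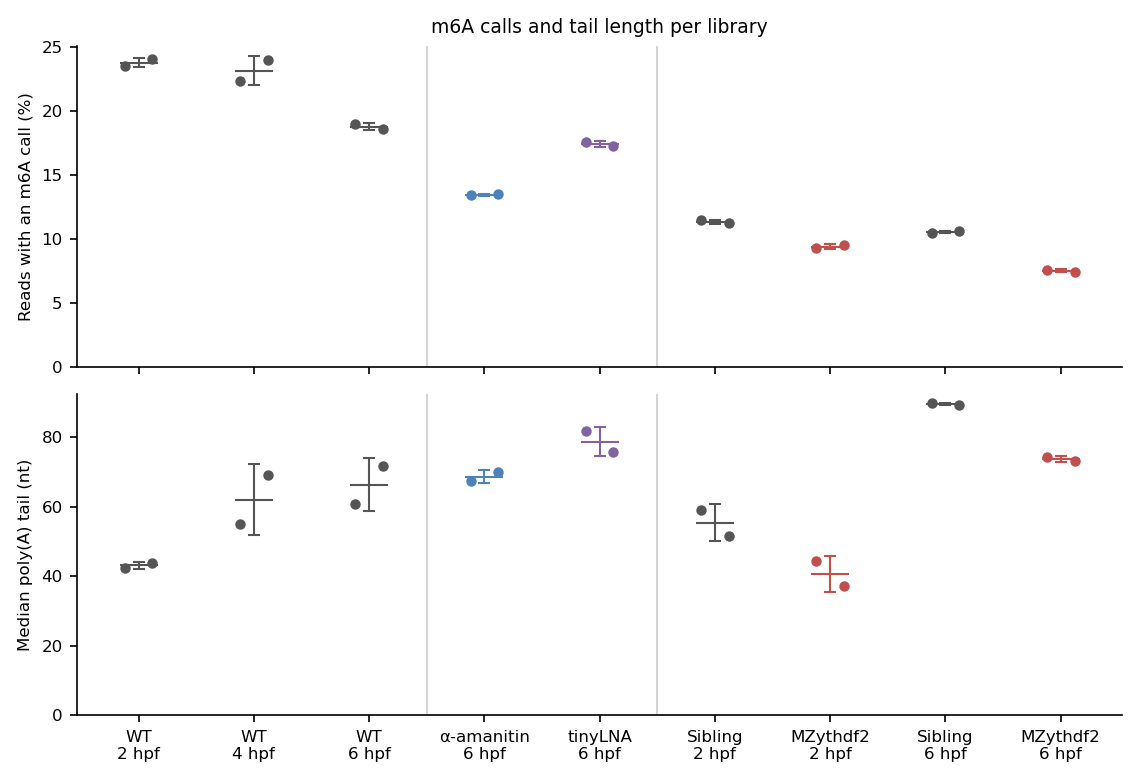
Reads with at least 1 m6A call (top, percent of reads) and median poly(A) tail of nuclear reads (bottom, nt) for each of the 18 libraries (points), with group mean and SD; vertical lines part the 3 tables, whose site lists differ. The modified share at 6 hpf was 7.53% in MZythdf2 and 10.5% in siblings, whose reads were longer.

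The α-amanitin comparison asks which mRNAs at 6 hpf differ when zygotic transcription is inhibited. Its control is wild type of the time course, for which the labels give no injection. Effects of injection, batch or stage are therefore not separated from those of the inhibitor. Against wild type at 6 hpf, 64 of 65 first-wave, 16 of 18 enveloping-layer and all 8 yolk-syncytial genes were lower, and 13 of 31 oocyte and 6 of 14 germ-plasm genes higher. These list calls passed at the preset correlation only. Reads of apoeb were 0 in both inhibitor libraries and 3439 ± 432 CPM in wild type (at least 1060-fold lower), and krt18a.1, a keratin of the enveloping layer, was at least 703-fold lower. In the other direction, buc was 543 ± 16.8 against 25.0 ± 8.05 (4.43, SE 0.34, adjusted p = 1.85e-07) and the early-embryo cyclin ccna1 was 2749 ± 170 against 373 ± 32.2 (2.88, SE 0.20, adjusted p = 8.23e-08).

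First-wave genes had a median of -9.43, -5.27 at bounds, with 1 higher and the same numbers adjusted over the list alone (adjusted p = 6.14e-48; adjusted p = 0.104 with an estimated correlation). The ventral homeobox gene ved, with 0 and 1 reads, was 1060-fold lower (95% interval 189 to 41700). Of 18 enveloping-layer genes 16 were lower and none higher, also adjusted over the list alone (median -10.30, -6.26 at bounds, adjusted p = 2.12e-29; adjusted p = 0.104 with an estimated correlation), with lye at least 625-fold lower. All 8 yolk-syncytial genes were lower, also adjusted over the list alone (median -10.05, -5.36 at bounds, adjusted p = 1.97e-08; adjusted p = 0.199 with an estimated correlation), gata6 at least 75.8-fold and hnf4a at least 51.4-fold. Ribosomal protein genes were lower for 64 of 85 and higher for 1, 66 and 2 when adjusted over the list alone (median -0.87, adjusted p = 8.95e-08; adjusted p = 0.262 with an estimated correlation). Oocyte genes were higher for 13 of 31 with 1 lower, the same adjusted over the list alone (median 0.67, adjusted p = 0.00266; adjusted p = 0.262 with an estimated correlation), the exception being fbxo5, an inhibitor of the anaphase-promoting complex (-4.07, SE 0.29). Germ-plasm genes were higher for 6 of 14 and lower for none, also adjusted over the list alone (median 0.72, adjusted p = 0.0144; adjusted p = 0.217 with an estimated correlation), with TDRD6 at 3.61 (SE 0.39).

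Of 7 p53 and stress genes 5 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.033; adjusted p = 0.243 with an estimated correlation): hspb1 at -6.95 (SE 0.30) and the p53 ligase mdm2 at -2.48 (SE 0.35), with mdm4 at 2.89 (SE 0.31). Cell-cycle genes were lower for 20 of 44 and higher for 6, 21 and 6 when adjusted over the list alone (median -0.50, adjusted p = 0.049; adjusted p = 0.243 with an estimated correlation), and this call ended without α-amanitin replicate 1 (0.0574, range over 7 alternatives 0.0173 to 0.0574). Helicase gene mcm3, with 1 read in each inhibitor library, was 187-fold lower (95% interval 51.6 to 1540). Among other lists, decay genes were higher for 11 of 23 with 3 lower (adjusted p = 0.0718), and the factors pou5f3 (-2.12, SE 0.24), vrtn (-3.43, SE 0.38) and foxh1 (-2.01, SE 0.24) were lower. The readers went apart, with igf2bp1 at -3.61 (SE 0.49) and ythdf3 at 2.79 (SE 0.35), and ybx1 was lower (-1.84, SE 0.19).

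Of 7904 tested genes 1849 were higher and 2076 lower, 3375 over 2-fold. Among the largest increases were zgc:163014 (5.36, SE 0.40), AKR1B1 (5.22, SE 0.42) and castor1 (4.90, SE 0.36), and asb11 (at least 389-fold) was among the largest decreases. Genes that fell over 2-fold from 2 to 6 hpf in the sibling libraries, which share no library with this comparison, were higher with α-amanitin for 1161 of 1814 and lower for 13 (median 1.32, camera p = 3.03e-42; p = 0.0167 with an estimated correlation). Genes with an m6A site differed from those without by 0.377 log2 (camera with preset correlation, p = 0.00966). Between matched genes the median difference was 0.029 and the test pointed down (camera with preset correlation, p = 0.864), and p = 0.258 with the read-length trend removed. At sites, where wild-type reads come from the table of the time course, 4 of 2779 were higher and 2 lower than in wild type, with rbm4.3 (chromosome 7, position 22795039) at 33.0% against 19.0% and the cyclin mRNA ccnb2 (chromosome 7, position 30630937) at 24.2% against 14.7%. This site count was 31 and 116 without wild-type replicates 1 and 3, 1 and 0 without α-amanitin replicates 1 and 2, and 2 without either tinyLNA library.

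The tinyLNA comparison asks which mRNAs at 6 hpf differ when miR-430, a zygotic microRNA that clears maternal mRNA, is blocked. Its control is the same wild type of the time course, so injection or batch cannot be told apart. Nor can stage: genes that rose over 2-fold from 2 to 6 hpf in siblings had a median of -0.25 with the tinyLNA. Those that fell had 0.49, against -0.04 for all genes. Increases outnumbered decreases, 687 against 91. The oocyte list as a whole did not pass, with a median of -0.02 and a mean of 0.25 (adjusted p = 0.244; adjusted p = 0.634 with an estimated correlation). In it 5 of 31 genes were higher, beside 687 of all 7904. Among those 5, ccna1 was 2330 ± 167 against 373 ± 32.2 CPM in wild type (2.64, SE 0.20, adjusted p = 6.27e-06). The mRNA of buc was 435 ± 196 against 25.0 ± 8.05 (4.11, SE 0.33, adjusted p = 6.53e-06), and that of the germ-plasm gene TDRD6 78.9 ± 2.19 against 5.08 ± 0.527 (3.92, SE 0.37, adjusted p = 1.77e-05). The Nodal ligand gene ndr1 and antagonist lft2, both known targets, were higher, ndr1 at 84.5 ± 23.4 against 18.7 ± 5.05 CPM and lft2 at 119 ± 0.678 against 42.1 ± 9.2.

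Known miR-430 targets were higher for 3 of 12 and lower for none, also adjusted over the list alone (median 0.42, adjusted p = 0.0323; adjusted p = 0.226 with an estimated correlation). The germ-granule gene tdrd7a was the other one (1.56, SE 0.33), and the list's call ended without wild-type replicate 3 (0.105, range over 7 alternatives 0.00175 to 0.105). Germ-plasm genes were higher for 4 of 14, also adjusted over the list alone (median 0.44, adjusted p = 0.000321; adjusted p = 0.141 with an estimated correlation), among them the maternal linker histone h1m (2.05, SE 0.26, adjusted p = 0.000148). Decay genes were higher for 9 of 23 and lower for none, 11 when adjusted over the list alone (median 0.49, adjusted p = 0.000943; adjusted p = 0.141 with an estimated correlation), with the Argonaute gene ago2 at 3.14 (SE 0.50) and the deadenylase gene pan2 at 1.62 (SE 0.30). First-wave zygotic genes were lower for 11 of 65 and higher for 2, 13 and 2 when adjusted over the list alone (median -0.40, adjusted p = 2.25e-05; adjusted p = 0.141 with an estimated correlation), such as the BMP antagonist szl (-1.93, SE 0.37). Of 18 enveloping-layer genes 2 were lower and 1 higher, 3 and 1 when adjusted over the list alone (median -0.40, adjusted p = 0.00535; adjusted p = 0.19 with an estimated correlation), with krt17 at -1.83 (SE 0.31) and the claudin cldn7b at 1.29 (SE 0.22). Ribosomal protein genes had a median of -0.31 (adjusted p = 2.25e-05; adjusted p = 0.496 with an estimated correlation) with 1 of 85 past the test, higher.

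Among maternal factors, nanog (1.26, SE 0.19), sox19b (1.75, SE 0.27) and the Nodal effector smad2 (1.99, SE 0.30) were higher. Further increases were ccnb2 (1.58, SE 0.21), ythdf3 (2.19, SE 0.36), mdm4 (1.99, SE 0.31), the glycogen synthase gys1 (4.85, SE 0.49), the mitochondrial fusion gene opa1 (4.47, SE 0.42) and cyclin gene ccnj (4.57, SE 0.46). Decreases included the neural factor sox2 (-2.55, SE 0.55; by DESeq2 its adjusted p was 0.384, range over 14 alternatives 1.56e-07 to 0.384) and the urea transporter slc14a2, 21.3-fold lower on 2 reads (95% interval 5.79 to 177). Of the 778 changed genes 697 moved over 2-fold, and the count was 1291 without wild-type replicate 3 and 502 without tinyLNA replicate 1. It was 497 by DESeq2, 499 without a filter on low counts, 511 with blocks and 518 with the 2 groups alone. Of 536 measured genes over 2-fold higher with the tinyLNA, 414 fell and 8 rose from 2 to 6 hpf in siblings (median -2.27, camera p = 1.33e-20; p = 0.000954 with an estimated correlation). Genes with an m6A site differed from those without by 0.198 log2 (camera with preset correlation, p = 0.000921), matched genes by -0.046 (p = 0.936), and p = 0.692 with the length trend removed. No site of 2779 passed the quasi-binomial test, with 117 at an unadjusted p under 0.05 and 17 by Fisher's exact test on pooled reads, and 26 and 36 passed without wild-type replicates 1 and 3.

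Between the injected groups, α-amanitin embryos had 779 genes higher and 1633 lower than tinyLNA embryos, a count of 1341 and 1530 without α-amanitin replicates 1 and 2. First-wave genes were lower for 64 of 65 and higher for 1, also adjusted over the list alone (median -9.09, -4.98 at bounds, adjusted p = 1.38e-58; adjusted p = 0.0592 with an estimated correlation), with the mesoderm factor tbx16 at least 276-fold lower. The mitotic inhibitor gene wee1 was lower (-6.07, SE 0.40), as was lft2 (at least 37.0-fold), and known miR-430 targets were lower for 6 of 12, 7 adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.162 with an estimated correlation). Oocyte genes were higher for 8 of 31 and lower for 2, 9 and 2 when adjusted over the list alone (median 0.64, adjusted p = 0.00402; adjusted p = 0.31 with an estimated correlation), such as cnpy1 (2.08, SE 0.33). Genes that fell in siblings were higher with α-amanitin than with the tinyLNA for 499 of 1814 and lower for 28 (median 0.69, p = 0.0317 with an estimated correlation). The modified share was 13.5 ± 0.0783% with α-amanitin and 17.5 ± 0.232% with the tinyLNA, and the median nuclear tail 68.6 ± 1.82 and 78.8 ± 4.21 nt (each exact permutation p = 0.333, the smallest 2 against 2 libraries can give). The share difference of -3.98 points was -1.61 with equal weight per gene, and the tail difference of -10.2 nt was -0.964 over genes with 20 reads.

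The MZythdf2 comparison at 2 hpf asks what differs in the maternal load without Ythdf2. Reads of ythdf2 (ENSDARG00000014498) were 0 in both mutant libraries and 15 in each sibling library (at least 15.1-fold lower). Ribosomal protein mRNAs were higher, 74 of 86 with none lower and 77 adjusted over the list alone (median 0.95, adjusted p = 7.5e-35; adjusted p = 0.282 with an estimated correlation). Without the S6 kinases and with the trend on read length removed their median was 0.34. The maternal activators pou5f3 and nanog were lower: pou5f3 was 247 ± 27.0 against 513 ± 66.8 CPM (-1.05, SE 0.18, adjusted p = 4.47e-05) and nanog 575 ± 16.2 against 888 ± 74.9 (-0.63, SE 0.15, adjusted p = 0.00185). MZythdf2 libraries had shorter reads (median 771 and 875 nt against 1330 and 1404), more mitochondrial reads (14.5% and 14.1% against 9.22% and 9.75%) and more reads without a tail (26.3% and 24.6% against 17.2% and 17.4%).

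Of the 9 maternal factors 5 were lower and none higher, also adjusted over the list alone (median -0.63, adjusted p = 0.0391; adjusted p = 0.411 with an estimated correlation), with sox19b at -0.70 (SE 0.17), a call that ended by DESeq2 (0.0997, range over 16 alternatives 0.00027 to 0.0997). The list's adjusted p over 9 alternatives ran from 0.0425 to 0.0812. It passed 0.05 without sibling 2 hpf replicate 2 (0.0675), MZythdf2 2 hpf replicates 1 and 2 (0.056 and 0.0696), sibling 6 hpf replicates 1 and 2 (0.0702 and 0.0683), MZythdf2 6 hpf replicates 1 and 2 (0.0605 and 0.0629) and with blocks (0.0812). For nanog the range was 0.000203 to 0.0524, the latter without sibling 2 hpf replicate 1. Oocyte genes went both ways, 9 of 32 higher and 3 lower, 10 and 4 adjusted over the list alone (adjusted p = 0.138), with buc at 0.96 (SE 0.15), a difference of -0.04 on uniquely assigned reads with a tail. Germ-plasm genes were higher for 1 and lower for 4 of 14, 1 and 6 adjusted over the list alone (adjusted p = 0.138), with ca15b at -1.40 (SE 0.18, adjusted p = 1.01e-06) and ccna1 of the oocyte list at -0.74 (SE 0.13). The m6A writers mettl14 (0.86, SE 0.23) and mettl16 (1.06, SE 0.25) were higher, calls that ended by DESeq2 (0.132 and 0.095, ranges over 16 alternatives 0.00134 to 0.132 and 4.66e-05 to 0.095). Other members of lists that changed were the poly(A)-binding gene pabpn1 (0.89, SE 0.20), the phosphatase cdc25b (0.78, SE 0.16), the helicase gene mcm7 (0.75, SE 0.18) and id3 (1.73, SE 0.33).

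Among the largest decreases were zgc:113425 (-4.07, SE 0.48), fam171a1 (-3.89, SE 0.58) and SOX11 (ENSDARG00000095743; -3.14, SE 0.32, adjusted p = 1.02e-08). Among the largest increases were MIF4GD (ENSDARG00000102080; at least 10.6-fold) and rin3 (13.9-fold, 95% interval 3.62 to 119). In total 809 of 6987 genes were higher and 766 lower, 1036 over 2-fold, a count of 922 without sibling 2 hpf replicate 1, of 338 by DESeq2 and of 949 on uniquely assigned reads with a tail. Genes with an m6A site differed from genes without one by -0.389 log2, with 8.6% of them higher against 24.6% (camera with preset correlation, p = 6.18e-08; p = 0.000827 between matched genes).

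At 6 hpf the MZythdf2 comparison asks which maternal mRNAs remain without Ythdf2. Of 32 oocyte genes 15 were higher, and of 9 yolk-syncytial genes 4 were lower. Both list calls passed at the preset correlation only, and the yolk-syncytial one ended without sibling 6 hpf replicate 2 (0.0637, range over 9 alternatives 0.00418 to 0.0637). The maternal claudin cldnd was 415 ± 105 against 59.6 ± 16.2 CPM in siblings (2.79, SE 0.33, adjusted p = 1.26e-07). Linker histone h1m was 835 ± 17.1 against 275 ± 42.4 (1.60, SE 0.20, adjusted p = 4.35e-07) and nanog 333 ± 11.4 against 108 ± 18.1 (1.63, SE 0.27, adjusted p = 4.09e-05). The apolipoprotein genes apoeb and apoc1 were lower, apoeb at 1955 ± 74.2 against 4654 ± 416 (-1.25, SE 0.14, adjusted p = 7.61e-08) and apoc1 at -1.51 (SE 0.17). Reads were again shorter in MZythdf2 (712 and 696 nt against 1104 and 1196), more of them mitochondrial (18.9% and 20.6% against 10.9% and 12.3%) and more without a tail (24.0% and 23.9% against 19.7% and 19.0%).

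The oocyte genes, with 1 lower, gave 18 higher and 1 lower when adjusted over the list alone (median 1.08, 0.98 at bounds, adjusted p = 6.8e-07; adjusted p = 0.0621 with an estimated correlation), including the egg-coat gene zp2.2 (at least 7.02-fold) and the oocyte kinase wee2 (1.95, SE 0.39). Ribosomal protein genes were higher for 55 of 86, 63 when adjusted over the list alone (median 0.51, adjusted p = 6.74e-18; adjusted p = 0.208 with an estimated correlation). Of 9 yolk-syncytial genes 4 were lower, and 4 lower and 1 higher when adjusted over the list alone (median -0.64, adjusted p = 0.00535; adjusted p = 0.194 with an estimated correlation), with mttp, which loads lipid onto lipoproteins, at -1.64 (SE 0.31). The value of mttp was -0.37 on uniquely assigned reads with a tail. Among 9 maternal factors 3 were lower and 1 higher, 4 and 1 when adjusted over the list alone (median -0.96, adjusted p = 0.0325; adjusted p = 0.327 with an estimated correlation), with pou5f3 at -1.28 (SE 0.16) and ctnnb1, which encodes β-catenin, at -1.33 (SE 0.17). Without sibling 6 hpf replicate 2 its adjusted p was 0.197 and without MZythdf2 6 hpf replicate 1 0.109 (range over 9 alternatives 0.01 to 0.197).

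First-wave genes were lower for 11 of 55 and higher for 6, 13 and 7 when adjusted over the list alone (adjusted p = 0.077), with the ventral repressor vox at 1.55 (SE 0.18). Enveloping-layer genes were lower for 5 of 18 and higher for 1 (adjusted p = 0.054), with krt5 at -0.88 (SE 0.15) and krt92 at 0.76 (SE 0.16; by DESeq2 its adjusted p was 0.0509, the upper end of a range from 3.51e-05). Cell-cycle genes went both ways, 9 of 43 higher and 7 lower, 11 and 10 adjusted over the list alone (adjusted p = 0.927), with the licensing inhibitor gmnn at 1.80 (SE 0.24, adjusted p = 1.03e-06). The cytoplasmic poly(A)-binding gene pabpc1a (-0.69, SE 0.14) and miR-430 target khdrbs1a (-0.73, SE 0.14) were lower. Residual ythdf2 reads, 3 and 5 against 17 and 16, gave -2.75 (SE 0.52, adjusted p = 0.000252).

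Among the largest differences were msh6, a mismatch-repair gene (3.62, SE 0.51), PCED1B (3.55, SE 0.50) and the DNA polymerase delta gene pold1 (36.7-fold, 95% interval 6.35 to 1470), all higher. Lower were pck2 (69.8-fold, 11.9 to 2820), PCDH1 (68.1-fold, 11.6 to 2760) and the histone gene hist2h3c (-3.23, SE 0.49). In total 681 genes were higher and 621 lower, 988 over 2-fold, with the median gene at 0.157. The count was 705 and 635 without sibling 6 hpf replicates 1 and 2, 522 and 741 without MZythdf2 6 hpf replicates 1 and 2, 459 by DESeq2 and 787 on uniquely assigned reads with a tail. Genes that fell over 2-fold from 2 to 6 hpf in the time course were higher for 133 of 1932 and lower for 32 (median 0.63, camera p = 0.00706; p = 0.00203 with an estimated correlation). The part higher was no larger than the 681 of all 6987 genes, while the part lower was smaller than the 621 of all. Genes that rose were lower for 450 of 1928 and higher for 176 (median -0.25, camera p = 2.03e-10; p = 0.00722 with an estimated correlation). Genes with an m6A site differed from genes without by -0.249 log2 (camera with preset correlation, p = 0.00465), -0.172 between matched genes (p = 0.0923) and -0.096 with the length trend removed (p = 0.272).

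**Figure D3:**
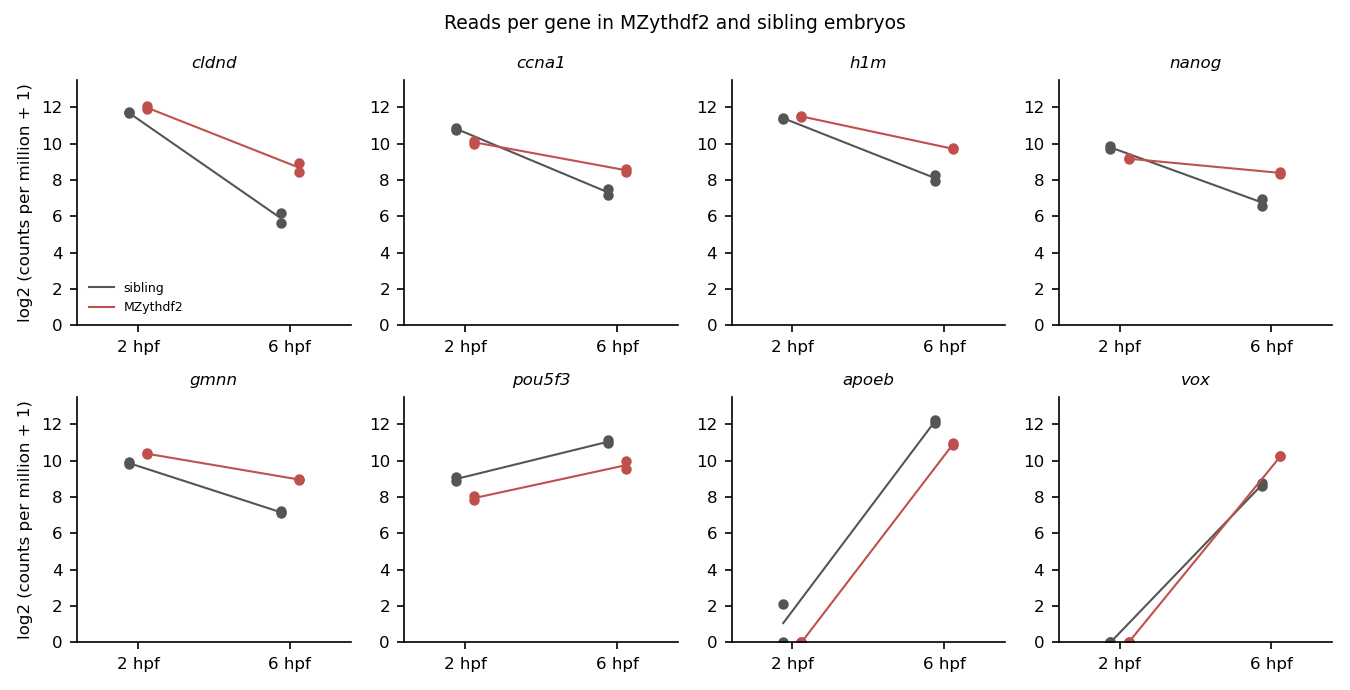
Level of 8 genes (y axis, log2 of CPM plus 1) in each sibling and MZythdf2 library (points) at 2 and 6 hpf (x axis). At 6 hpf both MZythdf2 libraries lie above both sibling libraries for cldnd (415 against 59.6 CPM) and nanog (333 against 108).

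The interaction asks whether the change from 2 to 6 hpf differs between genotypes. It passed for 99 genes, 58 of them with a weaker fall or stronger rise in MZythdf2 and 41 the other way, with the median gene at 0.129. The count was 36 by DESeq2, 39 on uniquely assigned reads with a tail and 152 with blocks. From 2 to 6 hpf cldnd went from 3311 to 59.6 CPM in siblings and from 4032 to 415 in MZythdf2 (2.51, SE 0.37, adjusted p = 6.18e-05). The cyclin gene ccna1 went from 1803 to 159 and from 1076 to 369 (1.95, SE 0.28, adjusted p = 6.18e-05). The linker histone h1m went from 2694 to 275 and from 2885 to 835 (1.50, SE 0.24, adjusted p = 0.000274), and nanog from 888 to 108 and from 575 to 333 (2.25, SE 0.31, adjusted p = 5.81e-05). The actin-binding gene marcksl1b went the other way (-3.37, SE 0.54, adjusted p = 0.000274). Counts were 47 without sibling 6 hpf replicate 2 and 15 and 38 without MZythdf2 6 hpf replicates 1 and 2.

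The oocyte list was positive, 5 of 32 members and 10 when adjusted over the list alone (median 0.90, adjusted p = 2.63e-08; adjusted p = 0.0423 with an estimated correlation). Ribosomal protein genes were negative, 2 of 86 and 21 when adjusted over the list alone (median -0.42, adjusted p = 4.56e-17; adjusted p = 0.193 with an estimated correlation). Germ-plasm genes were positive for 1 of 14, 2 adjusted over the list alone (median 1.12, adjusted p = 0.0295; adjusted p = 0.193 with an estimated correlation). That call ended without sibling 6 hpf replicate 2 (0.109) and MZythdf2 6 hpf replicate 2 (0.0651; range over 9 alternatives 0.0186 to 0.109). Poly(A)-binding and translation genes had no member past edgeR's test over all genes, and 3 negative and 1 positive adjusted over the list alone (median -0.48, adjusted p = 0.0296; adjusted p = 0.193 with an estimated correlation). That call ended without sibling 6 hpf replicate 1 (0.153) and MZythdf2 6 hpf replicates 1 and 2 (0.0615 and 0.0651; range over 9 alternatives 0.00824 to 0.153). Genes with an m6A site differed from those without by 0.205 log2 (camera with preset correlation, p = 0.0473), by 0.147 between matched genes (p = 0.127) and by 0.117 with the length trend removed (p = 0.315). Over the left-out libraries this p was 0.0701 without sibling 2 hpf replicate 2, 0.055 without MZythdf2 2 hpf replicate 2, 0.0796 and 0.0824 without the sibling 6 hpf libraries and 0.0706 and 0.0846 without the MZythdf2 6 hpf libraries.

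Within each genotype, the passage from 2 to 6 hpf was tested as in the time course. In siblings 1890 genes rose and 2230 fell (median gene -0.301), and in MZythdf2 1991 rose and 1981 fell. On uniquely assigned reads with a tail 2557 and 2457 changed, and by DESeq2 2583 in MZythdf2. First-wave genes rose for 52 of 55 in siblings (median 7.87, 4.92 at bounds) and 51 in MZythdf2 (7.35, 5.53 at bounds), and oocyte genes fell for 23 of 32 (median -3.01, -2.46 at bounds) and 20 (median -1.17). The buc relative buc2l was at least 17.3-fold lower in siblings and at least 37.9-fold in MZythdf2, and btg4 fell in both (181-fold, 95% interval 32.4 to 7180, in siblings and -4.54, SE 0.25, in MZythdf2). Of 71 list calls over all comparisons 13 held with an estimated correlation. They are the first-wave, enveloping-layer, yolk-syncytial, oocyte, germ-plasm and ribosomal protein lists in siblings (adjusted p from 0.00255 to 0.038) and in MZythdf2 (0.0173 to 0.0475), and the oocyte list in the interaction.

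The share of modified reads was lower in MZythdf2, whose reads were shorter, than in siblings. It was 9.41 ± 0.201% against 11.3 ± 0.183% at 2 hpf and 7.53 ± 0.118% against 10.5 ± 0.0760% at 6 hpf (SD, n = 2; each exact permutation p = 0.333, the smallest 2 against 2 can give). Among reads over 500 nt the differences were -0.734 and -1.99 points, and over 444 sites shared by the 3 site lists 2.92 and 1.4. Calls per kilobase of nuclear reads went the other way. They were 0.136 and 0.126 in MZythdf2 against 0.100 and 0.0948 in siblings at 2 hpf, and 0.125 and 0.127 against 0.108 and 0.106 at 6 hpf. Lists went both ways at 6 hpf: mRNAs of maternal factors carried a call on 11.4 ± 3.05% of reads in MZythdf2 and 31.2 ± 0.483% in siblings, those of decay genes on 21.4 ± 2.04% and 14.5 ± 1.2%, and those of yolk-syncytial genes on 19.2 ± 2.39% and 10.3 ± 1.1%. Single sites went up more often at 2 hpf, 15 of 480 against 2 down. Among the former were rimkla (chromosome 8, position 26885246) at 69.0% against 43.6% and RNA-binding syncrip (chromosome 20, position 2742122) at 47.2% against 33.0%, and 1 of those down was in STMN1, a tubulin regulator (chromosome 19, position 17208303), at 3.15% against 15.1%. At 6 hpf 1 site passed, in the splicing factor srsf2a (chromosome 12, position 31721331; 20.8% against 9.77%, adjusted p = 0.0182). The count at 2 hpf was 0 and 2 without sibling 2 hpf replicates 1 and 2, 11 and 4 without MZythdf2 2 hpf replicates 1 and 2, and 1 without either sibling 6 hpf library. At 6 hpf it was 3 without either MZythdf2 2 hpf library, 0 without either sibling 6 hpf library, and 0 and 4 without MZythdf2 6 hpf replicates 1 and 2, with 59 sites at an unadjusted p under 0.05 in the quasi-binomial test of all libraries.

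Tails were shorter in MZythdf2: the median nuclear tail was 40.7 ± 5.22 nt against 55.4 ± 5.26 nt at 2 hpf and 73.8 ± 0.778 against 89.5 ± 0.297 nt at 6 hpf (SD, n = 2; each exact permutation p = 0.333). Of 1361 genes 22 were shorter and 2 longer at 2 hpf, among the former mtdha (60.8 to 22.1 nt; -1.45, SE 0.11) and the cargo receptor tmed10 (103 to 39.7 nt). At 6 hpf 38 were shorter and 1 longer, with ARPP19, an inhibitor of a mitotic phosphatase (84 to 23.7 nt; -1.81, SE 0.15), the mitotic kinesin kif20a (126 to 42.6 nt) and cdc25b (119 to 47.3 nt) shorter. Cell-cycle mRNAs were shorter for 6 of 28 at 6 hpf. Ribosomal protein mRNAs went the other way at 2 hpf, at 32.5 against 27.7 nt over 78 genes, with 1 longer and 0 shorter past the test. The median difference per gene was -0.176 log2 at 2 hpf and -0.082 at 6 hpf. By limma, the 2 hpf count was 0 and 1 without sibling 2 hpf replicates 1 and 2, 0 without MZythdf2 2 hpf replicate 2, 7 and 8 without the sibling 6 hpf libraries and 8 and 7 without the MZythdf2 6 hpf libraries. The 6 hpf count was 4 without either sibling 2 hpf library, 7 without either MZythdf2 2 hpf library, 10 without either sibling 6 hpf library and 0 without either MZythdf2 6 hpf library, and the calls for tmed10, mtdha, ARPP19, kif20a and cdc25b were among those lost.

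Within a gene, reads with an m6A call had slightly shorter tails than reads without. The median difference over genes was -0.014 log2 over the 2 hpf libraries and -0.078 over the 6 hpf libraries, and lay below 0 in 17 of 18 libraries. Tails were shorter at each step from 0 to 1, 2 and at least 3 calls per read in 14 of 18 libraries by medians and in 11 by means, and by means 6 libraries stood above 0 at 3 or more calls. With mean tails the within-gene difference was above 0 in both 2 hpf sibling libraries and wild-type replicate 2 at 2 and 4 hpf. In wild type at 6 hpf replicate 3 it was 0.049. At 6 hpf the mean difference was -0.103 in MZythdf2 and -0.121 in siblings (exact permutation p = 0.333).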

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

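The tests of the m6A-site explanation and both tests on tails of modified reads were chosen only after the results were seen, as was the removal of the trend on read length. The first group of results stands here because the effect of the missing Ythdf2 differed between 2 and 6 hpf in the test of that difference itself. It passed in edgeR for 99 genes. Of the gene lists, the oocyte list passed (adjusted p = 2.63e-08), as did ribosomal proteins (adjusted p = 4.56e-17), germ plasm (adjusted p = 0.0295) and poly(A) binding and translation (adjusted p = 0.0296). With an estimated correlation the oocyte list stood at an adjusted p = 0.0423 and each of the others at an adjusted p = 0.193. The germ-plasm call also ended without sibling or MZythdf2 6 hpf replicate 2 (0.109 and 0.0651, range over 9 alternatives 0.0186 to 0.109). That of poly(A) binding ended without sibling 6 hpf replicate 1 (0.153) and MZythdf2 6 hpf replicates 1 and 2 (0.0615 and 0.0651, range over 9 alternatives 0.00824 to 0.153). In camera with preset correlation, genes that fell over 2-fold from 2 to 6 hpf in the time course passed (p = 0.000659), as did genes that rose there (p = 2.34e-10). The class with an m6A site stood at p = 0.0473 in camera with preset correlation, with a difference of 0.205. It stood at 0.127 between matched genes (0.147), 0.315 with the trend on read length removed (0.117) and up to 0.0846 with libraries left out, so that call depends on these choices.

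Single genes stand here by the same test, with log2 differences of differences. Positive were cldnd (2.51), ccna1 (1.95), h1m (1.50), nanog (2.25) and gmnn (1.29). Fitted values for genes without sibling reads at 6 hpf depend on the prior count and are no bounds: tent5c (7.47), si:ch211-147a11.3 (7.01), zp2.2 (6.43), patl2 (6.27) and gig2n (6.25). Negative were id3 (-2.55), ctnnb1 (-1.08), kif23 (-1.43), ccng2 (-5.16, on 1 sibling read at 2 hpf), KDM7A (-3.92) and marcksl1b (-3.37). Without sibling reads at 2 hpf, MIF4GD (ENSDARG00000102080; -7.57), acer1 (-6.58) and ENSDARG00000100836 (-5.50) also have fitted values that depend on the prior count. Of all these only cldnd, ccna1, h1m, nanog and marcksl1b passed the threshold under every alternative.

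The second group stands here because m6A calls appear outside the deposited sites, at positions no site test uses. The shares of modified reads and the tests of tails by calls count every call on a read, these included. Calls outside the sites are 0.412% of calls in the α-amanitin and tinyLNA table and 2.52% in the MZythdf2 table. The time course table has none.

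Of 86 ribosomal protein mRNAs 74 were higher in MZythdf2 at 2 hpf, where MZythdf2 libraries also had shorter reads. Against reads of ambiguous assignment or without a tail stands the median on uniquely assigned reads with a tail, 0.91 against 0.95 on all reads of 81 genes. Whether shorter reads raise short mRNAs in general cannot be told apart from a change of these mRNAs. The 83 ribosomal protein genes lay 0.40 above those 245 genes (SE 0.05 by resampling genes, without variation between libraries). This lies between the bounds of 0.2 and 0.5 set beforehand. With the trend on read length removed the ribosomal protein median was 0.34. Ythdf2 genotype stays open as a biological source, since read length goes with genotype in all 8 libraries.

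Of 32 oocyte mRNAs 15 were higher in MZythdf2 at 6 hpf. An earlier stage of the MZythdf2 embryos cannot be told apart from slower clearance. Genes that rose over 2-fold from 4 to 6 hpf had a median of -0.29, beside the bound of -0.3. Its SE by resampling 1747 genes was 0.02. Genes that fell then had 0.78 from fitted values, against 0.16 for all genes. Of the genes that rose, 1246 with an m6A site had a median of -0.39 and 483 without one 0.07. All genes with and without a site had 0.102 and 0.350. With the trend on read length removed the oocyte list's median was 0.83 (SE 0.20 by resampling genes) in place of 1.08, with 13 of 32 members higher (camera with preset correlation, p = 6.73e-07), which lies over 0.5 times the earlier value by less than 2 SE, so read length stays open for part of the difference. Neither of these SEs holds variation between libraries. Clearance through m6A sites may need Ythdf2, but in the interaction falling genes with a site differed from those without by 0.08 (camera with preset correlation, p = 0.868, pointing down). At 6 hpf alone they differed by -0.25 (camera with preset correlation, p = 0.00635), which goes against it, but they already differed by -0.39 at 2 hpf, so the explanation stays open.

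Within genes, modified reads had shorter median tails in all 10 libraries at 6 hpf, while by mean tails wild type at 6 hpf replicate 3 stood at 0.049. Longer modified reads do not account for the whole of it: within classes of read length the median difference was -0.071, below 0 in 10 of 10 libraries, from -0.132 to -0.011. In wild type at 6 hpf replicate 3, however, it shrank from -0.057 to -0.011, with a mean over genes of 0.034. Read length stays open for most of the difference in that library. Nor does Ythdf2 account for the whole of it, since the MZythdf2 library with the smaller difference stood at -0.094. MZythdf2 and sibling means of -0.103 and -0.121 had an exact permutation p = 0.333, the smallest 2 against 2 libraries can give. Other technical explanations, such as a link between m6A calls and tail estimates on the same molecule, were not tested, so a biological link stays a hypothesis.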

How the results depend on the processing

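Tests chosen only after the results were seen are those with the read-length trend removed, mitochondrial or ribosomal protein genes left out, sites by position, shared sites, nuclear reads, sites of at least 10% and replicates left out for lists. Each group has 2 libraries, so a left-out library leaves 1 that is assumed to vary like the other groups. The MZythdf2 and sibling libraries held fewer reads than the time course, and 480 sites and 1361 tails could be tested there against 12017 and 8189. Where a value below moved, the cause was not tested. Another probability threshold was not run.

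For genes with and without an m6A site, matching left fewer genes. From 2 to 6 hpf their difference stayed, at -0.414 against -0.411 on 4702 in place of 11940 genes, while the camera p with preset correlation was 0.363. For MZythdf2 at 6 hpf it was -0.172 against -0.249 (0.0923) and for the interaction 0.147 against 0.205 (0.127), on 2378 in place of 6965 genes. The matched test reversed in direction from 2 to 4 hpf (0.981), with α-amanitin (0.864) and with the tinyLNA (0.936). With the read-length trend removed the p was 0.188 from 2 to 6 hpf, 0.272 for MZythdf2 at 6 hpf, 0.315 for the interaction, 0.258 for α-amanitin and 0.692 for the tinyLNA. For the interaction it was 0.119 with sites only farther upstream and 0.183 without ribosomal protein genes. Left-out libraries moved the interaction's p between 0.0261 and 0.0846: 0.0701 without sibling 2 hpf replicate 2, 0.055 without MZythdf2 2 hpf replicate 2, 0.0796 and 0.0824 without sibling 6 hpf replicates 1 and 2, and 0.0706 and 0.0846 without MZythdf2 6 hpf replicates 1 and 2.

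Gene counts under DESeq2 were 338 for MZythdf2 at 2 hpf, 459 at 6 hpf, 36 for the interaction, 2583 for MZythdf2 over time and 497 for the tinyLNA. On uniquely assigned reads with a tail they were 949, 787 and 39 for MZythdf2 at 2 and 6 hpf and the interaction, and 2557 and 2457 over time in siblings and MZythdf2. There buc at 2 hpf reversed to -0.04. Replicates of different groups share only their numbers, with correlations of -0.397 to 0.244 between groups in the difference of their 2 replicates, and blocks by number gave 152 for the interaction and 511 for the tinyLNA. For the tinyLNA no filter gave 499 and the 2 groups alone 518. Of the list calls 13 held with an estimated correlation.

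Left-out libraries gave ranges of 603 to 1774 genes from 2 to 4 hpf (683 and 612 without 2 hpf replicates 1 and 2, 603 without 4 hpf replicate 2), 922 to 1751 for MZythdf2 at 2 hpf (922 without sibling 2 hpf replicate 1) and 522 to 1402 at 6 hpf (705 and 635 without sibling 6 hpf replicates 1 and 2, 522 and 741 without MZythdf2 6 hpf replicates 1 and 2). The interaction ranged from 15 to 144 (47 without sibling 6 hpf replicate 2, 15 and 38 without MZythdf2 6 hpf replicates 1 and 2), the tinyLNA from 502 to 1291 (502 without tinyLNA replicate 1, 1291 without wild-type replicate 3) and α-amanitin against tinyLNA from 1341 to 2817 (1341 and 1530 without α-amanitin replicates 1 and 2).

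For sites from 2 to 6 hpf Fisher's exact test gave 1683, the 2 groups alone 225 and blocks 44, and left-out libraries 6 to 225 (6 and 9 without 2 hpf replicates 1 and 2, 225 without either 4 hpf library, 20 and 10 without 6 hpf replicates 1 and 3). For MZythdf2 at 2 hpf a coverage of 10 gave 7, the 2 groups alone 6 and sites of at least 10% 11, and left-out libraries 0 to 17 (0 and 2 without sibling 2 hpf replicates 1 and 2, 11 and 4 without MZythdf2 2 hpf replicates 1 and 2, 1 without either sibling 6 hpf library). At 6 hpf these were 0 at a coverage of 10, 5 with blocks and 4 for sites of at least 10%, and 0 to 4 with libraries left out (3 without either MZythdf2 2 hpf library, 0 without either sibling 6 hpf library, 0 and 4 without MZythdf2 6 hpf replicates 1 and 2). For α-amanitin they were 75 by Fisher's exact test, 10 at a coverage of 10 and 2 with the 2 groups alone, and 0 to 116 (31 and 116 without wild-type replicates 1 and 3, 1 and 0 without α-amanitin replicates 1 and 2, 2 without either tinyLNA library). For the tinyLNA they were 17 by Fisher's exact test and 1 at a coverage of 10, and 0 to 36 (26 and 36 without wild-type replicates 1 and 3).

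Changed tails from 2 to 6 hpf ranged from 2542 to 5054 (2542 and 2826 without 2 hpf replicates 1 and 2), and dhx9 reversed to 0.85 with tails of 10 to 250 nt. For MZythdf2 at 2 hpf mean tails gave 2, 20 reads 57, tails of 10 to 250 nt 15 and blocks 9, and left-out libraries 0 to 34 (0 and 1 without sibling 2 hpf replicates 1 and 2, 0 without MZythdf2 2 hpf replicate 2, 7 and 8 without sibling 6 hpf replicates 1 and 2, 8 and 7 without MZythdf2 6 hpf replicates 1 and 2). At 6 hpf mean tails gave 10 and blocks 21, and left-out libraries 0 to 10 (4 without either sibling 2 hpf library, 7 without either MZythdf2 2 hpf library, 10 without either sibling 6 hpf library, 0 without either MZythdf2 6 hpf library).

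The decline of the modified share from 2 to 6 hpf was -2.96 points with equal weight per gene, -0.565 at shared sites and -4.03 on nuclear reads. For MZythdf2 at 6 hpf it was -3.49 on uniquely assigned reads with a tail, -2.25 with equal weight, -1.99 on reads over 500 nt and -2.53 on nuclear reads, and reversed to 1.4 at shared sites. At 2 hpf the values were -2.21, -0.734 on reads over 500 nt, -1.56 on nuclear reads and, reversed, 2.92 at shared sites. Between α-amanitin and tinyLNA they were -1.61 with equal weight, -4.31 on reads over 500 nt, -3.01 at shared sites and -3.7 on nuclear reads. The median tail per library for MZythdf2 at 6 hpf was -13.5 nt by means, -17.4 with 20 reads and -14.7 with tails of 10 to 250 nt, and between α-amanitin and tinyLNA -0.964 with 20 reads.

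Of 6221 values of named genes under an alternative 5928 kept direction and side of the threshold, 292 kept direction only and 1 reversed. Of 620 for lists these were 532 and 88, and of 246 for named tails 153 and 92, with 1 reversed.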

Other observations

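The tests on m6A-site clearance and on tails of modified reads were chosen only after the results were seen. The genes that changed with the injections were followed through the MZythdf2 comparison, which shares no library with them. Of 1320 measured genes over 2-fold higher with α-amanitin, 139 were higher and 14 lower in MZythdf2 at 6 hpf. Their median was 0.71 (camera p = 0.00036; p = 0.00366 with an estimated correlation). The part higher was close to the 681 of all 6987 genes. Here too cleared genes keep few reads at 6 hpf. Genes over 2-fold lower with α-amanitin were lower in MZythdf2 for 344 of 1321 and higher for 71 (median -0.39). Of 536 genes higher with the tinyLNA 47 were higher and 7 lower (median 0.40, camera with preset correlation, p = 0.0697), no larger a part than the 681 of all 6987 genes, whose median was 0.16. At 2 hpf 30 of the 536 were higher and 101 lower (median -0.16). In the interaction 11 were positive and 0 negative. The median of the 536 was 0.66 against 0.13 for all genes (camera p = 0.000166; p = 0.0215 with an estimated correlation). Genes that rose over 2-fold from 2 to 6 hpf in siblings were lower with α-amanitin for 1249 of 1632 and with the tinyLNA for 38.

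Shares of modified reads pooled over a list compare different genes where its reads come from other members. Reads of p53 and stress mRNAs had a call for 38.8% at 2 hpf and 14.1% at 6 hpf in wild type, while reads of hspb1 in replicate 1 went from 194 to 8059. For enveloping-layer mRNAs the share was 32.4% (11 genes) and 17.1% (20 genes). For known miR-430 targets it was 13.3% (13 genes) and 2.97% (14 genes). For first-wave mRNAs in α-amanitin embryos it was 65.6%, on 97 and 84 reads of only 13 genes. Over 2421 genes with at least 20 reads in both groups the share was 13.3% in siblings and 9.07% in MZythdf2 at 6 hpf. MZythdf2 reads given the sibling shares of their genes gave 11%, with 690 genes lower and 414 higher.

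A hypothesis set up here was that maternal mRNAs with an m6A site depend more on Ythdf2 for clearance than those without. Its test, a difference of 0.08 in the interaction, left this undecided (camera with preset correlation, p = 0.868, pointing down). Other values of the same split do not decide it, since the gap at 6 hpf was there at 2 hpf. Falling genes with a site differed from those without by -0.25 in MZythdf2 at 6 hpf (camera with preset correlation, p = 0.00635; p = 0.00947 with an estimated correlation). At 2 hpf they already differed by -0.39 (camera p = 1.18e-05; p = 0.00193 with an estimated correlation). In the same comparison at 2 hpf, genes with a site within 500 nt of the 3' end lay 0.241 log2 above genes with sites only farther upstream, and 0.356 at 6 hpf (camera with preset correlation, p = 0.00158 and 0.0031). No explanation of these differences was tested.

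The library of wild type at 4 hpf replicate 2 had 3.32% of reads on the strand opposite to the gene, against 0.549% to 0.904% in the other libraries.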
